A study of Arabidopsis thaliana with 17 samples.

How the data were processed

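Transcript levels were measured by stranded mRNA sequencing in 17 libraries from hypocotyls of Arabidopsis thaliana. Per the labels, seedlings were grown in the dark, the etiolated hypocotyls were cut, and the pieces were kept in the dark on plates of plain medium for 0, 1, 3, 6, 12 or 24 h. There were 3 libraries at each time point except 24 h, which had 2. The labels do not say whether libraries of the same time point came from separate batches of plants. They may be technical replicates, so the p-values measure only the spread between these samples.

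The authors provided a single table of 28642 genes by 17 columns. Its header names no unit. The deposited values were read as RPKM (reads scaled by the length of the gene model in kilobases and by the mapped reads of the library), because low values were whole multiples of a step set by the gene and the library and the column totals differed, which rules out TPM. The genome build is TAIR10 per the labels, and the aligner, the read counter and the handling of reads that fit several genes are not given in the sources used here. Dividing the values by these steps gave whole read numbers for 24834 of the 24834 genes above 0 (tolerance 0.01), and 3808 genes were at 0 in every library. Gene lengths were searched for whole read numbers, so this is a weak check for genes above 0 in few libraries. Of these lengths 3160 equalled those of a later annotation, which gave a length for 28001 genes. The read totals rest on the value given by 1406 of 16975 genes. The recovered totals were 20740957 mapped reads in 0 h replicate 1, 11760741 and 11736568 at 24 h, and 7717255 to 7872179 in the other 14 libraries, a ratio of 2.69 between highest and lowest. Between 98.74% and 99.04% of mapped reads fell on listed genes. For a transcript of 1 kb, 3 reads correspond to 0.1446 to 0.3887 RPKM, which covers counting error only. Sequencing reads are not independent molecules.

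The choice of test, filter, gene lists, named genes and first set of alternatives was made before the data were examined. That plan held a branch for counts and a branch for normalized values, and the second was used because the table turned out to hold RPKM. Genes were tested if they reached an RPKM of at least 1 in at least 2 libraries (19656 genes, 68.6%). Values were log2 transformed after adding 1. A linear model with time point as a factor of 6 levels was fitted to all 17 libraries with limma 3.58.1 (R 4.3.3) with an intensity trend and robust moderation, so that 24 h shared its estimate of the spread with the other time points. Each later time point was compared with 0 h, neighbouring time points from 1 h on were compared with each other, and an F test asked for any change over the course. P-values were adjusted by Benjamini and Hochberg over the genes tested and called at 0.05. Log2 changes are differences of mean log2(RPKM + 1), which are smaller than the log ratio of means for genes near 0. In tests on simulated data for 1 h against 0 h, 35.8% of genes changed 1.5-fold were called, 79.1% of those changed 2-fold and 93.9% of those changed 4-fold, against 0.02% of unchanged genes. For 24 h against 12 h, with 2 libraries at 24 h and 3 at 12 h, the shares were 25.4%, 62.7%, 97.0% and 0.04%. The simulation changed only 66 or 67 genes at each fold, drawn from genes above a low read level, and the members of a list. In the data 72.9% of tested genes were called at 1 h, which loosens the adjusted threshold. A shift of most genes was not simulated, so these shares may not hold for the real data.

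27 gene lists with 382 members were fixed by locus identifier. They cover early wound and touch transcription factors, jasmonate, ethylene, cytokinin synthesis, cytokinin response, auxin synthesis and transport, auxin response, callus and reprogramming regulators, S phase, G2 and M phase, ribosome biogenesis, heat shock, low oxygen, abscisic acid and dehydration, phenylpropanoid and lignin, suberin, tryptophan and camalexin, elongation and primary wall, brassinosteroid synthesis, carbon starvation and dark response, light harvesting, circadian clock, xylem, phloem, shoot apex, root hair and seed storage. Of the members, 341 were tested, and 25 lists had the minimum of 3 tested members. Each was compared with all other tested genes by limma's camera with a preset correlation between genes of 0.01, adjusted over 125 tests. Camera with an estimated correlation, and fry, which asks only whether a list's genes move on balance in a direction, were run beside it. In simulated data for 1 h against 0 h, a list of 26 members shifted 2-fold had an adjusted p of 6.8e-54, and 0 of 24 other lists were called by camera with the preset correlation. The simulation does not model genes that vary together between libraries.

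Genes named in a comparison with 0 h were the 8 largest rises and the 8 largest falls among called genes with a gene symbol and a mean log2 value of at least 1, for which every library of the later time point lay on the same side of every 0 h library. For each step between neighbouring time points the 3 largest of each direction were taken. For each called list up to 4 members with the largest change in the called direction were taken, for the tissue and clock lists up to 3 at any time, and for the callus and reprogramming list all tested members. Some are described and the rest are summarised. Symbols were taken from a later annotation release, in which 28009 of the 28642 identifiers were found, so no positions are given. Of the tested genes, 8442 had a symbol.

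The other settings fixed at that stage were quantile normalization, median centring, a filter that asked only for a value above 0 in any library, a filter of at least 5 in at least 2 libraries, a pseudocount of 0.1, a fit of only the libraries compared, a stricter threshold (adjusted p under 0.001 and a change of at least 2-fold), replicate number as a block, and leaving out each library in turn. Voom on the recovered reads, thinning all libraries to the same depth, and leaving out the 0 h and 12 h libraries that stood apart were added after seeing the data. Figures were drawn with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.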

Results

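Gene expression was followed from the cut to 24 h later in dark-grown hypocotyls, a system in which callus forms at the wound. The 17 libraries fell into 6 time points, with n = 3 at 0, 1, 3, 6 and 12 h and n = 2 at 24 h, at depths of 7717255 to 20740957 mapped reads. Levels are given as mean RPKM ± SD over the libraries of a time point, and changes as log2 differences with their standard error (SE). All later time points were set against the same 0 h libraries, and there were no uncut hypocotyls kept for the same hours, so time since cutting and time in culture were not separated by the design.

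Libraries of the same time point lay close together. Pearson correlations across tested genes were 0.975 to 0.991 within 0 h and 0.981 to 0.992 within the later time points. The mean correlation with 0 h libraries was lowest at 3 h and 6 h (0.816 at each), and was 0.830 at 1 h, 0.874 at 12 h and 0.878 at 24 h. Genes within a library are not independent replicates, so these values describe similarity only.

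**Figure D1:**
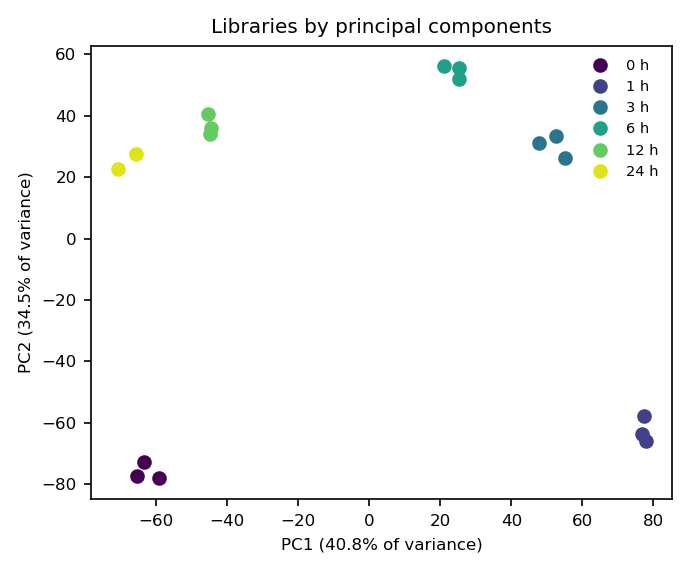
Each point is a library, coloured by time point, placed by the first principal components of log2(RPKM + 1) of the tested genes. PC1 holds 40.8% of the variance and PC2 34.5%, and libraries of the same time point lie together.

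Over the whole course 18316 of 19656 tested genes (93.2%) passed the F test. Of these, 4743 had their highest mean at 0 h, 2310 at 1 h, 2091 at 3 h, 1611 at 6 h, 2474 at 12 h and 5087 at 24 h. Compared with 0 h, 3573 genes were higher and 10755 lower at 1 h, 5430 and 7732 at 3 h, 5939 and 7288 at 6 h, 6770 and 5471 at 12 h, and 7121 and 4552 at 24 h. Changes of at least 2-fold among them were fewer, with 2017 higher and 2180 lower at 1 h, 2288 and 2755 at 3 h, 2367 and 2706 at 6 h, 2160 and 1599 at 12 h, and 2198 and 1614 at 24 h. At 1 h these became 2527 and 1062 with median centring, 2212 and 1473 with quantile normalization and, chosen after the data were seen, 2306 and 3436 with voom, so their balance has no fixed direction. With median centring the excess turned at 3, 6 and 24 h as well, to 2517 higher and 2383 lower, 2548 and 2448, and 1787 and 1946. The median log2 change of all tested genes was -0.36 at 1 h, -0.12 at 3 h, -0.07 at 6 h, 0.06 at 12 h and 0.14 at 24 h. The balance of higher and lower genes moved with the scaling. At 1 h the share of called genes that were higher was 24.9%, and 42.4% with median centring (4909 higher, 6673 lower). At 12 h the balance turned, with 6027 higher and 6147 lower with median centring and 5988 and 6226 with quantile normalization, and at 24 h it narrowed to 5860 and 5593 with median centring. Because of these shifts, many medians of gene lists are given relative to the median of all tested genes and are then called relative, and other medians are without that subtraction. Counts of list members that rose or fell carry no such correction and are to be read against the counts over all 19656 tested genes.

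**Figure D2:**
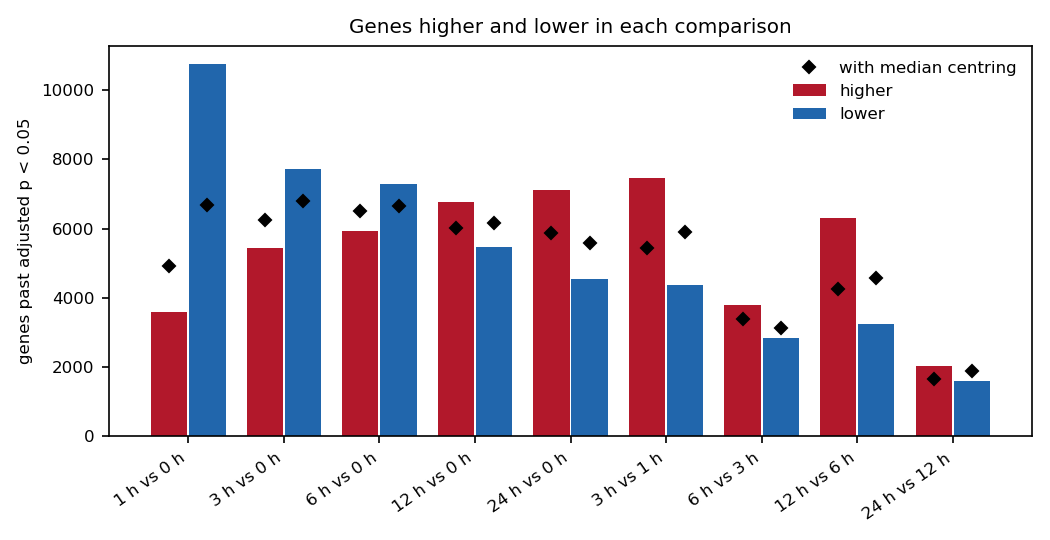
Bars count genes higher (red) and lower (blue) past an adjusted p of 0.05 in each comparison, and diamonds give the same counts with median centring. The largest shift between scalings is at 1 h against 0 h, where 10755 genes were lower and 6673 with median centring.

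The comparison of 1 h with 0 h asks which transcripts differ within 1 h of the cut. TAT3 (AT2G24850), a tyrosine aminotransferase induced by jasmonate, rose from 0.975 ± 0.782 to 681.4 ± 98.9 RPKM, a log2 change of 8.49 (SE 0.23, adjusted p 2.36e-13). Of the enzymes of jasmonate synthesis, LOX3 (AT1G17420) rose from 0.425 ± 0.0347 to 301.6 ± 37.9 RPKM (7.72, SE 0.14), AOC2 to 560.8 ± 64.6 and AOC1 to 493.6 ± 90.5. The transcription factor genes ERF109 (AT4G34410) and WRKY40 (AT1G80840) rose from 1.33 ± 1.23 to 493.4 ± 69.6 and from 4.92 ± 2.06 to 1136.4 ± 109.7 RPKM. The other large rises were in FAMT, a methyltransferase gene (526.8 ± 104.1 RPKM at 1 h), and HSP17.4, a small heat shock protein gene (369.6 ± 76.9). The largest falls were smaller. GDU4, from a family that governs amino acid export, fell from 68.2 ± 9.95 to 6.89 ± 0.727 RPKM (-3.13, SE 0.11), and GDU1 fell by 2.80. PXY (AT5G61480), the receptor kinase gene of the vascular cambium, fell from 61.1 ± 4.18 to 7.88 ± 0.714 RPKM (-2.81, SE 0.10). SEN1 and DIN10, which are induced in the dark, fell by 3.01 and 2.81, from 0 h levels that varied between libraries (367.9 ± 169.6 and 254.5 ± 122.5 RPKM).

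At 3 h IGMT2 (AT1G21120), a methyltransferase of indole glucosinolates, rose from 3.44 ± 0.629 to 847.5 ± 33.5 RPKM (7.59, SE 0.19, adjusted p 9.67e-14). PAD3 (AT3G26830), which completes camalexin, rose from 0.465 ± 0.354 to 138.0 ± 0.705 RPKM, and the dirigent protein gene DIR5 from 2.94 ± 1.91 to 437.5 ± 39.4. The transcription factor gene RAP2.6 rose from 5.59 ± 2.32 to 763.7 ± 83.2 RPKM. ERD9, a glutathione transferase gene, reached 402.9 ± 21.1 RPKM. Among the largest falls, BXL1 (AT5G49360), a xylosidase, fell from 1105.1 ± 283.7 to 34.1 ± 3.71 RPKM (-4.95, SE 0.22), BGAL4 from 1191.1 ± 288.3 to 58.0 ± 2.37 and BGAL7 from 106.3 ± 21.4 to 2.95 ± 0.667. UMAMIT17, an amino acid transporter, fell by 4.89, and LAX2, an auxin influx carrier, fell from 60.2 ± 1.2 to 2.32 ± 0.222 RPKM (-4.21, SE 0.13).

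At 6 h the largest rises included 2 glutathione transferase genes. GSTF7 (AT1G02920) rose from 38.4 ± 3.75 to 6502.5 ± 984.7 RPKM (7.36, SE 0.12, adjusted p 1.78e-15) and GSTF6 (AT1G02930) from 13.8 ± 5.76 to 4416.9 ± 790.6 (8.29, SE 0.26). TI1, a protease inhibitor, rose from 3.53 ± 1.93 to 819.4 ± 52.4 RPKM. BIP3 (AT1G09080), a chaperone of the endoplasmic reticulum, rose from 0.0684 ± 0.118 RPKM, a level below 3 reads per kilobase, to 199.0 ± 25.8. SWEET11, a sugar transporter, fell from 554.0 ± 98.0 to 18.6 ± 3.11 RPKM (-4.82, SE 0.16), and the pectin methylesterase gene ATPMEPCRD from 802.2 ± 83.2 to 37.4 ± 5.39. GSTF6 and GSTF7 are close in sequence, as are AOC1 and AOC2, and the split of reads within each pair depends on an assignment rule that is not known here.

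At 12 h and 24 h the largest rises included genes that stayed high and genes of later function. TI1 reached 1119.1 ± 46.2 RPKM at 12 h and 634.3 ± 62.8 at 24 h. EARLI1 (AT4G12480), a lipid transfer-like wall protein gene, rose from 103.1 ± 11.7 to 5044.8 ± 440.5 RPKM at 12 h (5.60, SE 0.23) and 6170.8 ± 666.5 at 24 h (5.89, SE 0.26). The chitinase gene EP3 reached 51.3 ± 5.73 RPKM at 12 h, and the abscisic acid receptor gene PYL6 reached 27.2 ± 1.44 at 24 h (4.34, SE 0.24). The tonoplast aquaporin gene TIP2;3 (AT5G47450) fell from 372.2 ± 72.5 to 8.92 ± 3.21 RPKM at 12 h and 2.79 ± 2 at 24 h (-6.71, SE 0.39, adjusted p 6.04e-09), and TIP2;2 from 752.9 ± 34.1 to 20.9 ± 4.59 at 24 h. SEN1 fell to 3.47 ± 0.563 RPKM at 24 h (-6.28, SE 0.38). PRP2 and XTH17 also passed at 12 h, with 0 h levels that spread widely (299.1 ± 216.6 and 142.6 ± 116.8 RPKM).

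Regulators tied to callus formation and reprogramming differed in timing. WIND1 rose modestly, from 185.0 ± 19.9 RPKM at 0 h to 283.3 ± 24.0 at 1 h (0.61, SE 0.08), and stood at 255.2 ± 5.71 at 24 h (0.47, SE 0.09). WIND2 fell, to 35.2 ± 0.904 RPKM at 3 h from 100.2 ± 19.2 (-1.46, SE 0.11), and WIND3 fell at 1 h (-1.48, SE 0.18) and rose at 24 h (1.03, SE 0.20). The ethylene response factor genes ERF114 and ERF115 were highest at 1 h, rising from 1.46 ± 0.573 to 124.3 ± 24.3 RPKM (5.68, SE 0.19) and from 2.53 ± 1.05 to 45.1 ± 5.09 (3.74, SE 0.18). RAP2.6 was highest at 3 h and had returned to 14.9 ± 1.5 RPKM at 24 h, whereas ERF113 rose to 259.7 ± 34.9 at 3 h and 342.7 ± 46.4 at 24 h (2.34, SE 0.14). Among PLETHORA genes, PLT5 was highest at 1 h (10.1 ± 1.09 RPKM), and PLT3 rose from 2.59 ± 0.126 to 17 ± 0.316 at 24 h (2.32, SE 0.17) and PLT7 from 0.950 ± 0.363 to 5.91 ± 0.411 (1.84, SE 0.20). LBD16, which acts downstream of auxin in root founder cells, rose from 6.78 ± 2.85 to 40.7 ± 3.99 RPKM at 6 h (2.49, SE 0.22), and WOX13 to 24.4 ± 0.710 at 1 h (0.90, SE 0.11). LBD29 rose at 1 h (1.27, SE 0.22) and fell by 1.04 at 6 h. LBD17, WOX5 and WOX11 rose at 3 h from levels under 1 RPKM, by 1.07, 1.85 and 1.16. LBD18 fell by 0.83 at 24 h, to 0.289 ± 0.227 RPKM. ANAC071 changed by 0.94 (SE 0.34) at 3 h and by 0.30 or less at the other times. Of the 18 tested members, 12, 14, 13, 12 and 12 rose at 1, 3, 6, 12 and 24 h, and 2, 1, 2, 2 and 3 fell, with the same counts adjusted over the list alone. The list was called higher at every time, with adjusted p between 1.33e-05 and 0.0469, and adjusted p between 0.268 and 0.428 with an estimated correlation. The call at 24 h ended with replicate number as a block (adjusted p 0.0511). WIND4, ESR1, ESR2, PLT1, PLT2, BBM, LEC1 and LEC2 were below the filter and were not tested.

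**Figure D3:**
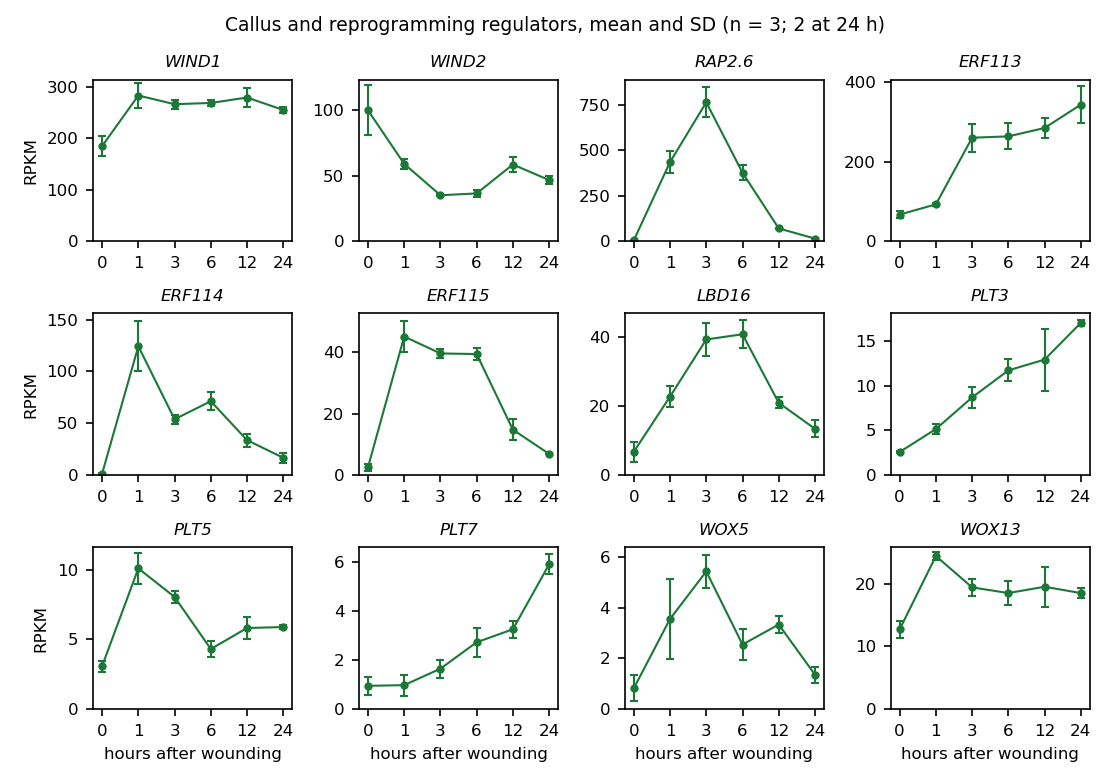
Points are mean RPKM and bars the SD (n = 3, and 2 at 24 h) of 12 callus and reprogramming regulators against hours after wounding, with time points evenly spaced. ERF114, ERF115 and PLT5 are highest at 1 h, RAP2.6 and WOX5 at 3 h, and PLT3, PLT7 and ERF113 at 24 h.

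Cell cycle genes were low until 6 h and above the 0 h level at 24 h. KNOLLE, the syntaxin of the cell plate, fell from 41.2 ± 2.71 to 3.64 ± 0.176 RPKM at 6 h (-3.18, SE 0.19), and CYCA1;1 from 11.6 ± 0.783 to 0.658 ± 0.166. CYCD3;1, a D-type cyclin, fell from 45.7 ± 3.07 to 14.6 ± 1.85 RPKM at 1 h and 6.62 ± 0.943 at 6 h (-2.62, SE 0.11). Of 20 genes of G2 and M phase, 19, 20, 20 and 13 fell at 1, 3, 6 and 12 h and 0 rose, and 16 rose at 24 h, when 0 fell. CYCB2;1 rose from 2.12 ± 0.222 to 7.02 ± 0.458 RPKM at 24 h (1.37, SE 0.16). Of 17 genes of S phase and DNA replication, 17 fell at each of 1, 3 and 6 h, 10 rose and 2 fell at 12 h, and 14 rose at 24 h (15 adjusted over the list alone), among them MCM5 (8.29 ± 0.553 to 19.3 ± 0.0693 RPKM). The medians relative to all genes were -0.60, -1.78, -2.35, -0.63 and 0.60 for the first list and -0.74, -1.18, -0.95, 0.54 and 0.73 for the second. Both were called at every time, with adjusted p between 1.60e-08 and 0.0198, except S phase at 12 h (adjusted p 0.0608). The call of G2 and M phase at 24 h was lost with voom (0.0620). With an estimated correlation their adjusted p was 0.268 to 0.585.

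Ribosome biogenesis genes rose earlier. FIB2 (fibrillarin) rose from 29.9 ± 3.14 to 110.1 ± 6.5 RPKM at 6 h and 156.8 ± 15.6 at 12 h (2.35, SE 0.11), and BRX1-2 from 18.5 ± 2.22 to 71.6 ± 2.88 at 12 h. Of 19 members, 16 fell at 1 h, 18 rose at 3 h and 19 rose at each of 6, 12 and 24 h, with relative medians of -0.10, 1.11, 1.39, 1.33 and 1.11. The rises were called with adjusted p between 1.79e-10 and 3.36e-08 (adjusted p 0.268 with an estimated correlation). The lower call at 1 h (adjusted p 0.0314, and 0.607 with an estimated correlation) was lost with quantile normalization (0.0706) and median centring (0.154).

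**Figure D4:**
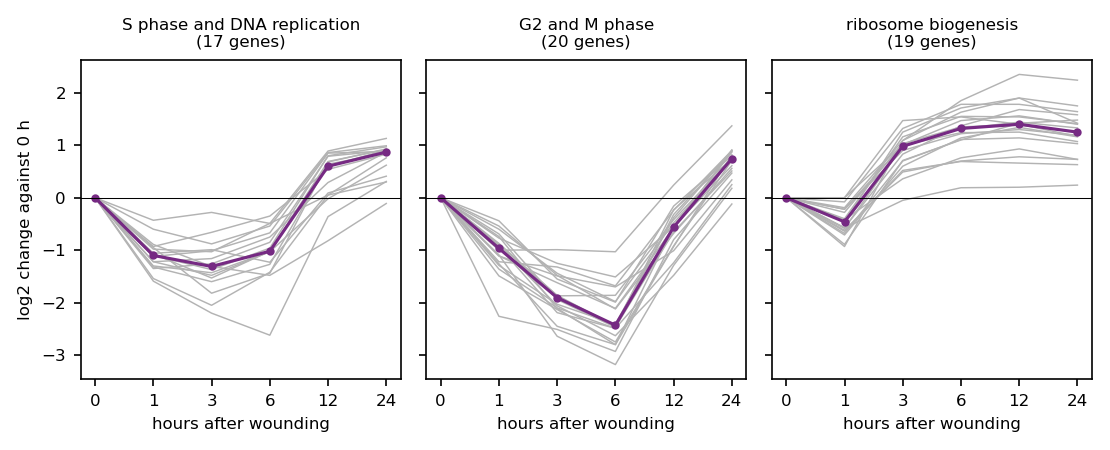
Grey lines are the log2 change against 0 h of each tested member and the purple line is their median, against hours after wounding with time points evenly spaced. The G2 and M phase median falls to -2.43 at 6 h and stands at 0.74 at 24 h, and the ribosome biogenesis median is 0.98 at 3 h.

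Most genes of the jasmonate and early wound lists rose at 1 h. JAZ8, a repressor gene of jasmonate signalling, rose from 0.208 ± 0.0316 to 181.6 ± 20.4 RPKM at 1 h and was at 5.19 ± 3.1 at 12 h. VSP2 rose later, from 10.8 ± 3.06 to 78.1 ± 23.8 RPKM at 12 h. Of 26 tested jasmonate genes, 23 rose at 1 h and 21 at each of 3, 6 and 12 h, and 0 and then 3 fell (4 at 3 h adjusted over the list alone). The relative medians were 5.30, 2.18, 1.68 and 0.87. The list was called at these times with adjusted p between 1.76e-24 and 0.000573 (adjusted p between 0.0722 and 0.336 with an estimated correlation). At 24 h 9 rose and 8 fell, the median was 0.05 and turned to -0.09 with quantile normalization, and the list was not called (adjusted p 0.880). Of 23 early wound and touch transcription factor genes, 19 rose at 1 h, 18 at 3 h and 17 at 6 h, and 0, 5 and 5 fell. WRKY18 rose from 17 ± 1.03 to 887.3 ± 77.6 RPKM at 1 h. The list was called at 1, 3 and 6 h (adjusted p 2.56e-16, 1.12e-06 and 0.000145, and 0.268, 0.285 and 0.390 with an estimated correlation). It was not called at 12 h (9 rose, 6 fell, adjusted p 0.274) or 24 h (7 rose, 5 fell, adjusted p 0.536).

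Heat shock genes rose without a heat treatment in the labels. HSP17.6A rose from 0.666 ± 0.473 to 271.7 ± 85.6 RPKM at 1 h and HSFA2 from 2 ± 2.12 to 305.5 ± 50.7. Of 14 members, 14, 11, 11 and 10 rose at 1, 3, 6 and 12 h and 0, 1, 1 and 2 fell (11 rose at 12 h adjusted over the list alone). The list was called at these times with adjusted p of 2.46e-12, 0.000155, 6.94e-05 and 0.0314. With an estimated correlation the adjusted p was 0.268, 0.369, 0.352 and 0.609. The relative medians were 6.23, 3.22, 3.59 and 1.49. Without the subtraction the median at 1 h was 5.87, and 6.22 with a member listed at 0 at 0 h held at its detection bound, and 3.09 and 3.51, 3.52 and 3.87, and 1.56 and 1.83 at 3, 6 and 12 h. HSP17.6C stood at 274.6 ± 175.0 RPKM at 6 h, a wide spread. At 24 h 6 rose and 2 fell (7 and 3 adjusted over the list alone), and the list was not called (adjusted p 0.335).

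Phenylpropanoid genes rose broadly from 3 h on, and tryptophan and camalexin genes from 1 h on. PAL2, at the entry to phenylpropanoids, rose from 53.8 ± 11.9 to 1006.5 ± 62.8 RPKM at 3 h (4.22, SE 0.13), C4H from 188.1 ± 22.7 to 1681.3 ± 119.6 and CAD5 from 235.8 ± 25.5 to 1862.6 ± 148.9. Of 14 phenylpropanoid and lignin genes 13 rose at each of 3, 6, 12 and 24 h and 0 fell, with relative medians of 2.1, 1.89, 1.15 and 1.16. The calls had adjusted p between 3.36e-08 and 1.63e-05 (adjusted p between 0.274 and 0.369 with an estimated correlation). At 1 h 6 rose and 3 fell (2 adjusted over the list alone), and the call (adjusted p 0.0124, and 0.607 with an estimated correlation) was lost with quantile normalization (0.217), where the median turned from 0.11 to -0.04. TSA1, of tryptophan synthesis, rose from 51.8 ± 6.87 to 1223.2 ± 184.3 RPKM at 6 h (4.53, SE 0.14) and ASA1 from 15.2 ± 0.835 to 254.0 ± 37.8 at 3 h. Of 7 tryptophan and camalexin genes 5, 6, 7, 6 and 5 rose at 1, 3, 6, 12 and 24 h (7 at 12 h adjusted over the list alone) and 0 fell. This list was called at each time with adjusted p between 3.83e-05 and 0.0316 (adjusted p between 0.274 and 0.507 with an estimated correlation). Of 12 suberin genes 9 rose and 1 fell at 24 h, but the list was not called then (adjusted p 0.0790) or earlier. ASFT (16.9 to 93.5 RPKM) and CYP86B1 (0.607 to 9.71 RPKM) are given as examples chosen after their values were seen.

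Auxin and brassinosteroid genes were lower. The repressor gene IAA3 fell from 88.8 ± 7.22 to 4.52 ± 0.267 RPKM at 6 h (-4.02, SE 0.15) and GH3.3, an auxin-conjugating enzyme gene, from 27.7 ± 15.4 to 1.02 ± 0.311 at 24 h. SAUR24 was at 5.96 ± 5.06 RPKM at 0 h and listed at 0 in all 6 h libraries. Of 20 auxin response genes 17, 18 and 18 fell at 6, 12 and 24 h and 0 rose. Their relative median was -1.67, -1.75 and -1.93. Without the subtraction it was -1.75, -1.69 and -1.79, and -1.88, -1.75 and -1.93 with members listed at 0 held at their detection bound. The calls had adjusted p of 0.00110, 1.10e-05 and 7.28e-07, and 0.517, 0.390 and 0.336 with an estimated correlation. At 3 h 13 fell and the list was not called (adjusted p 0.0611). At 1 h 7 rose and 9 fell (10 adjusted over the list alone), and the median of -0.54 and the mean of 0.14 differed in sign. YUC9, of auxin synthesis, fell from 4.40 ± 1.18 to 0.235 ± 0.143 RPKM at 24 h. Of 12 auxin synthesis and transport genes 9, 9 and 7 fell at 6, 12 and 24 h and 2, 3 and 2 rose. The calls had adjusted p of 0.0386, 0.0386 and 0.0126 (0.274, 0.274 and 0.268 with an estimated correlation), and the call at 12 h was lost with median centring (0.0515). At 1 h and 3 h 7 and 8 fell (9 at 3 h adjusted over the list alone) and the list was not called. BR6OX2, of brassinosteroid synthesis, fell from 106.3 ± 10.8 to 20.3 ± 2.36 RPKM at 1 h (-2.33, SE 0.12). Of 5 tested members of that list 5, 4, 5, 5 and 5 fell at 1, 3, 6, 12 and 24 h. The calls had adjusted p between 0.00281 and 0.0279, and between 0.268 and 0.277 with an estimated correlation.

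Other hormone and stress lists changed in part. ACS2, of ethylene synthesis, rose from 0.943 ± 0.717 to 82.3 ± 4.70 RPKM at 6 h (5.50, SE 0.25). Of 15 ethylene genes 10 rose and 1 fell at 3 h (2 fell adjusted over the list alone), and 9 rose and 1 fell at 6 h, with calls at adjusted p of 0.0126 and 0.0419 (0.336 and 0.412 with an estimated correlation). The 6 h call was lost with median centring (0.0513). At 1, 12 and 24 h 6, 3 and 5 rose and 3, 6 and 3 fell (5 rose at 1 h adjusted over the list alone), without a call, and at 12 h the median of -0.27 and the mean of 0.23 differed in sign. LTI30, a dehydrin gene, rose from 23.5 ± 6.46 to 632.7 ± 47.6 RPKM at 1 h (4.72, SE 0.25), and NCED3, of abscisic acid synthesis, from 8.27 ± 1.51 to 69.0 ± 4.12. RD29A fell from 94.4 ± 44.4 to 4.65 ± 0.451 RPKM and RD22 from 694.9 ± 71.1 to 63.7 ± 1.44 at 24 h. Of 13 abscisic acid and dehydration genes 7 rose and 2 fell at 1 h and 0 rose and 10 fell at 24 h. The calls were in opposite directions, with adjusted p of 0.000253 and 1.09e-05 (0.285 and 0.268 with an estimated correlation), and there was no call at 3, 6 or 12 h. The cytokinin synthesis, cytokinin response, low oxygen, and elongation and primary wall lists were not called at any time. At 6 h 5 of 14, 3 of 12, 4 of 9 and 3 of 11 of their members rose and 6, 4, 1 and 8 fell (3 fell in cytokinin response adjusted over the list alone). For elongation and primary wall 7 fell at 12 h and 5 at 24 h (8 and 6 adjusted over the list alone).

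Genes of the dark and starvation response were lower at all times. DIN10, a raffinose synthase gene induced in the dark, fell from 254.5 ± 122.5 to 13.8 ± 2.24 RPKM at 3 h (-4.01, SE 0.29). BCAT2, which breaks down branched amino acids, fell from 43.2 ± 21.3 to 3.01 ± 0.966 RPKM at 24 h (-3.37, SE 0.33). Of 13 members 10, 10, 10, 12 and 12 fell at 1, 3, 6, 12 and 24 h and 1, 1, 1, 0 and 0 rose (at 6 h 2 rose and at 24 h 13 fell adjusted over the list alone). The list was called from 3 h on with adjusted p of 0.00658, 0.00780, 1.71e-06 and 8.22e-08, and 0.505, 0.507, 0.277 and 0.273 with an estimated correlation, but not at 1 h (adjusted p 0.144). Of 12 clock genes 10, 7 and 9 fell at 3, 12 and 24 h and 0, 1 and 1 rose, with calls at adjusted p of 0.00780, 0.0305 and 0.000883 (0.336, 0.428 and 0.274 with an estimated correlation). RVE4 fell from 62.0 ± 11.8 to 14.5 ± 1.54 RPKM at 24 h (-2.01, SE 0.15). The clock list was not called at 1 h or 6 h.

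Of 8 xylem and secondary wall genes 5, 2, 6 and 5 fell at 1, 3, 6 and 12 h, and all 8 at 24 h. Of all 19656 tested genes 10755, 7732, 7288, 5471 and 4552 were lower at these times. The secondary wall cellulose synthase genes CESA7 and CESA8 fell from 21.7 ± 2.22 to 2.96 ± 0.826 and from 16.9 ± 2.44 to 2.29 ± 0.540 RPKM at 24 h, and the laccase gene LAC4 from 56.6 ± 2.25 to 10.7 ± 0.730. The list was called at 24 h only, with a relative median of -2.11 (adjusted p 1.71e-06, and 0.274 with an estimated correlation). Of 5 phloem genes 2 fell at 24 h, among them SEOR2 (115.1 ± 10.2 to 45.3 ± 9.21 RPKM), and of 4 shoot apex genes 3 fell at 3 h, among them KNAT1 (87.6 ± 8.04 to 34.3 ± 1.80 RPKM). Neither list was called at any time. At 1 h 1 phloem gene fell, and 0 adjusted over the list alone. LHCA2, of light harvesting, fell from 14.6 ± 2.35 to 2.23 ± 0.285 RPKM at 6 h. Of 15 light harvesting and photosynthesis genes 8 fell and 1 rose at 6 h, with a call at adjusted p 0.0496 (0.635 with an estimated correlation) that was lost with quantile normalization (0.0655). At 12 h 7 rose and 2 fell, and 5 rose and 4 fell without 12 h replicate 1. The list was not called at the other times. The root hair and seed storage lists had only 1 and 2 tested members and no list test. EXPA18 was listed at 0 at 0 h and reached 1.55 ± 0.519 RPKM at 1 h, and SESA1 rose from 0.0832 ± 0.0914 to 4.96 ± 1.83 RPKM at 3 h.

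**Figure D5:**
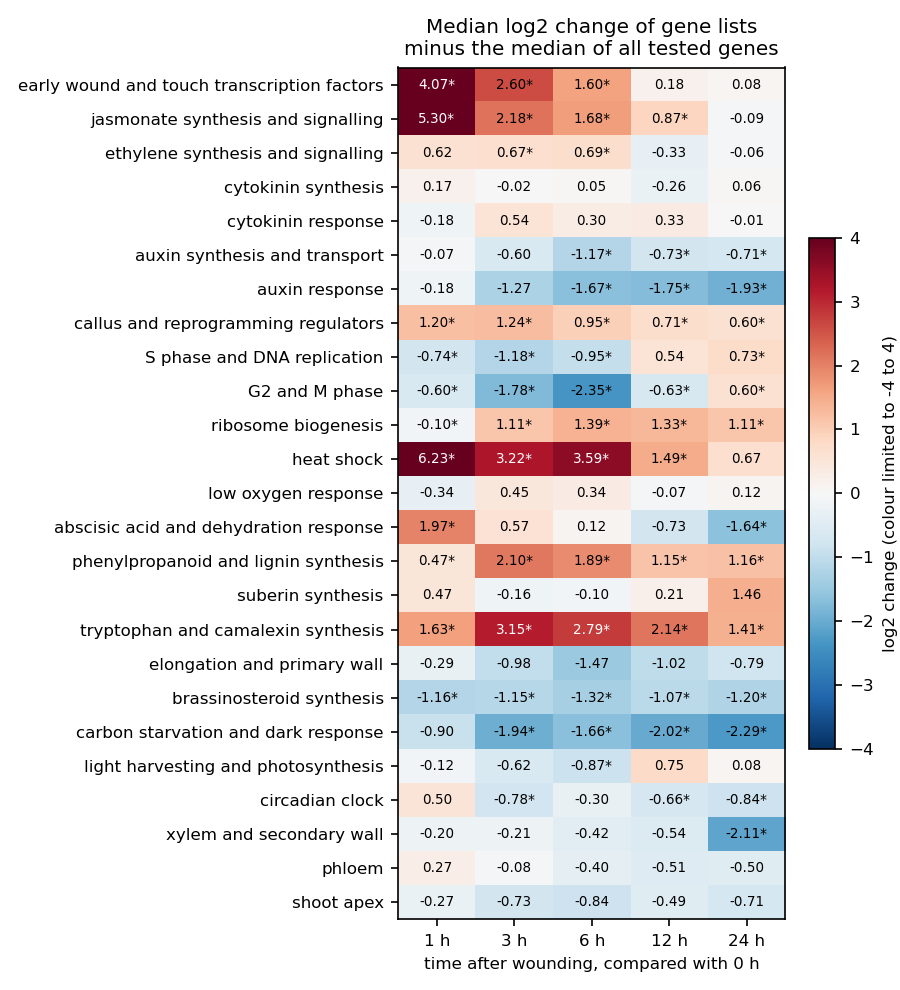
Each cell is the median log2 change of a gene list against 0 h, minus the median of all tested genes, and a star marks lists called with a preset correlation (64 of 125 tests). The largest values are at 1 h, with 6.23 for heat shock and 5.30 for jasmonate. Before that subtraction, medians near 0, such as phenylpropanoid at 1 h and jasmonate at 24 h, change sign with quantile normalization.

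In all, 64 of the 125 list tests were called by camera with a preset correlation. With an estimated correlation 0 were called by camera, with 22 at an unadjusted p under 0.05, and fry called 101. Counts adjusted over the list alone differed in 16 of the 125 tests. The list calls are weak evidence. In a test added after the data were seen, libraries were regrouped at random after the mean of each time point was removed. This gave a median of 28 list calls (7 to 53) and at most 1 gene in the F test. Counts of members that rose or fell are not firmer evidence for a list. Members that vary together add up in them too, and 10755 of 19656 tested genes were lower at 1 h.

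Steps between neighbouring time points show when changes happened. From 1 h to 3 h 7470 genes rose and 4368 fell, a share of 63.1% higher that became 48.1% with median centring (5450 higher, 5889 lower). The amino acid transporter gene LHT1 rose from 9.71 ± 4.37 to 491.1 ± 42.1 RPKM (5.60, SE 0.27) and RNS1, an RNase, from 30.6 ± 14.2 to 1278.2 ± 90.4. MYB95 fell from 79.5 ± 8.42 to 1.16 ± 0.514 RPKM (-5.25, SE 0.21) and ORA47, a regulator of jasmonate synthesis, from 106.3 ± 14.8 to 2.41 ± 0.205. From 3 h to 6 h 3781 rose and 2840 fell. BIP3 rose from 1.27 ± 0.695 to 199.0 ± 25.8 RPKM (6.5, SE 0.36) and SARA1A from 0.807 ± 0.699 to 63.3 ± 5.62, whereas MDHAR fell from 613.7 ± 66.0 to 47.1 ± 3.95 (-3.67, SE 0.30). From 6 h to 12 h 6314 rose and 3237 fell, a share of 66.1% higher that became 54.1% with quantile normalization (4724 higher, 4016 lower) and 48.1% with median centring (4246 higher, 4578 lower). PSAH2, of photosystem I, rose from 1.15 ± 0.329 to 18.5 ± 8.01 RPKM (3.12, SE 0.26), and HSP17.6A fell from 227.6 ± 141.1 to 22.1 ± 10.5. LHCB1.3 stood at 37.0 ± 45.4 RPKM at 12 h, with 89.4 in replicate 1 against 8.90 and 12.7 in the others. From 12 h to 24 h 2032 rose and 1595 fell, the fewest of these steps, and with median centring the balance turned to 1659 higher and 1875 lower. Among them were KCS12 (1.63 ± 0.484 to 19.9 ± 2.31 RPKM) and CML41 (46.4 ± 9.86 to 5.79 ± 1.18 RPKM). The counts of this step depend on the 24 h libraries, with 1017 higher and 878 lower without replicate 1 and 948 and 787 without replicate 2.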

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

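Voom on the recovered reads, thinning to equal depth, and leaving out 0 h replicate 3 and 12 h replicate 1 together were chosen after the data were seen, and the other settings before. Counts of genes past the threshold, without a fold limit, stayed within 1.5 times the reported ones under quantile normalization, both filters, the pseudocount of 0.1, the fit of only the libraries compared, the replicate block, voom, thinning and the omission of those 2 libraries. Counts with a fold limit of 2 were made again only under quantile normalization, median centring and voom, and at 1 h voom gave 3436 lower. With median centring, 6673 genes were lower at 1 h and 3472 genes had their highest mean at 1 h. The stricter threshold asks for more, and gave 1912 higher and 2025 lower at 1 h, 2200 and 2569 at 3 h, 2281 and 2513 at 6 h, 2017 and 1439 at 12 h, and 2019 and 1395 at 24 h. For the steps it gave 1625 and 1349 (1 h to 3 h), 295 and 450 (3 h to 6 h), 928 and 754 (6 h to 12 h), and 301 and 223 (12 h to 24 h). It left 8333 genes changed over the course, with highest means in 2513, 1488, 1011, 721, 893 and 1707 at 0, 1, 3, 6, 12 and 24 h. Leaving out each library in turn gave 948 to 1748 genes higher and 787 to 1401 lower from 12 h to 24 h, the lowest without 24 h replicate 2. A lone 24 h library is then assumed to vary like the other groups. The other counts stayed within 1.5 times, with 18026 to 18263 genes changed over the course and 59 to 65 lists called.

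Of the 64 list calls, camera with an estimated correlation kept 0 (22 tests had an unadjusted p under 0.05), and fry called 101. The ethylene list at 12 h, not called by camera in the main test and pointing down, was called upward by fry (adjusted p 0.00962), a test of another question, and the cause was not tested further. The other settings called 62 to 67 lists, with some different calls and no called list reversed. Calls ended for ribosome biogenesis and phenylpropanoid genes at 1 h and light harvesting at 6 h (quantile normalization), ribosome biogenesis at 1 h, ethylene at 6 h and auxin synthesis at 12 h (median centring), ethylene, auxin synthesis and light harvesting at 6 h (filter on any value above 0), and ribosome biogenesis at 1 h and auxin synthesis at 12 h (filter at 5). They also ended for light harvesting at 6 h and the callus regulators at 24 h (replicate block, adjusted p 0.0511 for both), ethylene at 6 h and G2 and M phase at 24 h (voom), light harvesting at 6 h (thinning), and ethylene at 6 h (without the 2 libraries). New calls were auxin response at 3 h (quantile normalization, median centring, filter above 0, block, and without the 2 libraries), carbon starvation at 1 h (both scalings), the clock at 6 h and S phase at 12 h (quantile normalization and filter above 0), suberin at 24 h (median centring and filter above 0), ethylene at 1 h (block), and light harvesting at 3 h, low oxygen at 6 h and abscisic acid at 12 h (without the 2 libraries). Leaving out 1 library ended the light harvesting call at 6 h in 12 of 17 fits. It ended calls for the callus regulators at 24 h (without 0 h replicate 1, 0 h replicate 3, 1 h replicate 2 or 24 h replicate 1), auxin synthesis at 12 h (0 h replicate 1 or 1 h replicate 2) and 6 h (1 h replicate 2), heat shock at 12 h (0 h replicate 1), the clock at 12 h (0 h replicate 2), ethylene at 6 h (0 h replicate 3) and ribosome biogenesis at 1 h (1 h replicate 2). It gave new calls for auxin response at 3 h (0 h replicate 3 or 3 h replicate 2), low oxygen at 6 h and abscisic acid at 12 h (0 h replicate 3), ethylene at 1 h (0 h replicate 1 or 1 h replicate 3), carbon starvation at 1 h (0 h replicate 1), the clock at 6 h (0 h replicate 1 or 6 h replicate 3), xylem at 6 h (6 h replicate 3), light harvesting at 3 h (12 h replicate 1) and suberin at 24 h (1 h replicate 3 or 24 h replicate 2). Replicate number as a block was among the settings chosen before. In the data 14 of 17 libraries lay closest to libraries of their own number, so libraries of the same number may share a batch. The 40 correlations between same-number libraries of different times, after removing time, ran from -0.17 to 0.34 with 16 above 0.1. They were not set against pairs of different number, so they cannot exclude a shared batch. The main model did not take the numbers as pairs, and the replicate block kept 62 of its 64 list calls. The 426 results for named genes kept their direction under each setting that tested them. Those no longer past the threshold were 11 with voom, 5 with only the libraries compared, 3 without the 2 libraries that stood apart, and 1 each with the pseudocount of 0.1, quantile normalization and thinning. In leave-one-out fits 21 results fell short and 2444 did not change their call. With the filter at 5, 393 could be tested, and these did not change.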

Other observations

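The tests in this part, and the gene families in it, were chosen or their criteria written down after the results they concern had been seen.

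12 gene families were examined after the largest changes had been seen, each at 5 times, with camera adjusted over 60 tests. The adjustment does not correct for that choice, so the adjusted p-values of these families are not comparable with those of the fixed lists. Chaperones of protein folding in the endoplasmic reticulum rose together. BIP1 went from 112.7 to 737.2 RPKM at 6 h, BIP2 from 66.9 to 669.2 and CNX1 from 110.8 to 703.0. Of 10 tested members 7, 10, 10, 10 and 9 rose at 1, 3, 6, 12 and 24 h and 1 fell at 1 h (camera adjusted p 4.64e-08 at 6 h, and 0.121 with an estimated correlation). Proteasome subunits rose from 6 h on, with 34, 35 and 33 of 37 higher and 1, 0 and 0 lower at 6, 12 and 24 h. Before that 29 were lower and 1 higher at 1 h, and 12 lower and 7 higher at 3 h. The family was not called then (camera adjusted p 0.0541 and 0.642). Their median log2 change at 6 h was 0.65, and 0.72 relative to all genes (camera adjusted p 3.13e-09, and 0.188 with an estimated correlation). Of 41 glutathione transferase genes 23, 25, 25, 26 and 20 rose and 9, 6, 7, 5 and 6 fell. The adjusted p with an estimated correlation was 0.0316, 0.0420 and 0.0454 at 1, 3 and 6 h, and 0.0992 and 0.249 at 12 and 24 h. Of 54 WRKY genes 28, 34, 34, 31 and 30 rose and 11, 7, 8, 4 and 3 fell (adjusted p 0.0246, 0.0316, 0.0766, 0.121 and 0.121 with an estimated correlation). In indole glucosinolate synthesis 6, 6, 6, 6 and 4 of 7 genes rose and 0, 0, 0, 1 and 0 fell (median 2.68 at 3 h). The adjusted p with an estimated correlation was 0.0316, 0.0223, 0.0316, 0.121 and 0.335, and at 24 h the family was not called with a preset one either (0.279). MYB51 went from 32.4 to 406.1 RPKM at 3 h. The 4 sulfate reduction genes rose at 3, 6, 12 and 24 h and 3 of them at 1 h, among them APR3 from 53.9 to 442.5 RPKM at 3 h (adjusted p 0.183 to 0.283 with an estimated correlation). Of 30 UMAMIT transporters 21, 22, 24, 19 and 20 fell and 3, 0, 0, 3 and 3 rose, and from 3 h on the adjusted p with an estimated correlation was 0.0196 to 0.0223, while at 1 h the family was not called (camera adjusted p 0.1, and 0.219 with an estimated correlation). Of 18 core histone genes 15, 16, 14, 9 and 2 fell and 1, 0, 0, 3 and 11 rose. The family was called at 1, 3 and 6 h (camera adjusted p 0.00971, 3e-05 and 0.000405, and 0.249, 0.121 and 0.178 with an estimated correlation) but not at 12 or 24 h (0.148 and 0.0516). Of 24 autophagy genes 19, 16, 13, 15 and 16 fell and 0, 2, 4, 3 and 1 rose. Camera gave adjusted p of 0.0189, 0.0210, 0.0757, 0.000225 and 8.37e-07, so that 6 h was not called, and 0.249, 0.249, 0.357, 0.121 and 0.0499 with an estimated correlation. Xyloglucan endotransglucosylase and aquaporin genes were not called at 1 h (camera adjusted p 0.910 and 0.555) or 3 h (0.148 and 0.316) and were called lower at 6, 12 and 24 h. At 12 h 14 of 22 and 13 of 25 fell and 3 and 6 rose (0.00504 and 0.00505, and 0.195 and 0.203 with an estimated correlation). With an estimated correlation the adjusted p was 0.235 and 0.283 at 6 h and 0.249 and 0.203 at 24 h. Of the aquaporin genes 11 fell and 8 rose at 24 h, with a median of -0.12. All 7 further carbon starvation genes fell at every time, and the family was called from 3 h on but not at 1 h (camera adjusted p 0.0611), with 0.121 to 0.440 with an estimated correlation. The medians of these families kept their sign under quantile normalization and median centring at the times given, but relative to all genes the proteasome median at 1 h was 0.08.

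More genes were lower than higher at 1 h, 10755 against 3573. A difference in depth is argued against, since with all libraries thinned to the same number of reads 25.1% of called genes were higher, close to the 24.9% reported. A few genes taking many of the reads at 1 h may be part of it, since the 100 genes with the largest gain took 1.8% of reads at 0 h and 11.9% at 1 h, and scaling to the reads outside them raised the share to 31.9% (4134 higher, 8828 lower), while median centring gave 42.4%. The 2017 genes that rose at least 2-fold at 1 h, picked for that rise, took 5.2% of reads at 0 h and 30.8% at 1 h, which alone would change the share left to all other genes by -0.45 (log2), against the median change of -0.36. These are unlike measures, since -0.45 is for a share of reads and -0.36 is a median of log2(RPKM + 1) over all tested genes (-0.43 with voom). Shares of reads sum to a whole, so they cannot tell a rise of these genes from a wider fall in transcripts. A wider fall stays open, since no spike-in or cell number was analysed here.

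Genes of green tissue and of the glyoxylate cycle were high in 12 h replicate 1. Of 17 such genes 17 were higher there than in every other library, 15 of them at least 2-fold. The 17 were listed after that library had been seen, so their count describes the pattern and is no test of it. They include genes of the Calvin cycle such as RBCS1A and PRK, which are not among the 14 below. ICL stood at 108.3 RPKM against 3.52 and 4.05 in the other 12 h libraries, RBCS1A at 96.2 against 2.48 and 3.36, and 51 genes in this library were at least 2-fold above every other library, against 35 or fewer elsewhere. Light as the only source is argued against by MLS, an enzyme gene of lipid use that exceeded the other 12 h libraries by 3.38 (log2). This cannot exclude light reaching that sample as well. The light signal genes ELIP1, ELIP2 and HY5 stood at 0.575, 0.63 and 18.4 RPKM there, none above the highest other 12 h library. ELIP1 and ELIP2 were under 1 RPKM there. Cotyledon or leaf material in that library is a possible source, with 7 of 14 Calvin cycle and photorespiration genes higher there than in every other library (3 at most in another library), although 9 of the 14 were at an RPKM of at least 1 in both other 12 h libraries too, and CA1, abundant in green leaves, was at 0.633, so this stays open, and no biological explanation was tested. Without that library the light harvesting list rose from 6 h to 12 h by a median of 1.26 instead of 1.75, with 12 of 15 genes higher either way.

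Carbon starvation genes were lower after the cut. High values in 0 h replicate 3 alone are argued against, although its mean log2 value for the list was 6.27 against 5.23 and 5.65 in the other 0 h libraries, since without it the median change was still -1.53 or lower from 3 h to 24 h. The hour of collection alone is argued against by the median of -2.15 at 24 h, the same time of day as 0 h. The clock may still have differed in pieces kept in the dark, since 9 of 12 clock genes were lower and 1 higher at 24 h. An effect of the clock therefore cannot be excluded. A better sugar supply after cutting could not be judged, because only 4 of 8 sugar induced genes were tested and 1 of them was at least 2-fold higher at 24 h (NIA1 by 1.36, with APL3 at 0.70, BAM5 at 0.12 and APL4 at -0.48).

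Other groupings of the libraries were fitted. For 3 against 3 libraries there are 10 splits, so the share is never under 0.1, and the real split was in each case the 1 split of 10 with as many genes. Fitted on those 6 libraries, it called 13241, 12562, 12510 and 11298 genes at 1, 3, 6 and 12 h against 0 h, and 11132, 6567 and 9373 for the steps from 1 h to 3 h, 3 h to 6 h and 6 h to 12 h, while the highest other split called 0 in limma at the adjusted threshold. In 100 regroupings of the 17 libraries, the real one included, 1 gave as many genes in the F test as the real 18316. The highest other gave 68. The other splits and regroupings mix time points within a group, which widens the spread, so they could hardly call genes. The libraries may also be technical replicates, so chance differences between batches of plants cannot be excluded. For the gene lists 4 of the 100 gave as many calls as the real 64, the highest other gave 67, and the median of the others was 49. These regroupings still hold the differences between times, so the same 99 other groupings were fitted again after the mean of each time point was removed. Camera with a preset correlation then called a median of 28 lists (7 to 53), and the F test at most 1 gene. Members of a list thus vary together apart from time, for reasons that were not tested, so the list calls are weak evidence. Counts of members that rose or fell are open to the same limit.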
